A study of Homo sapiens with 4 samples.

How the data were processed

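RNA of A549 cells, an established human lung adenocarcinoma line, was sequenced in 4 libraries, with 1 library per group. Per the labels' protocols, solid-type and acinar-type tumor cells were cut by laser microdissection from A549 xenografts grown in mice, and GFP-labelled A549 cells were sorted from 3D tumor colonies grown with or without cancer-associated fibroblasts (CAFs). Libraries were made with a TruSeq RNA kit, per the same protocols. Whether the solid and acinar cells came from the same tumor or mouse is not given in the sources used here, so differences between them include any difference between tumors or animals. Groups were taken from the sample titles. The culture titled as a mix was read as the one grown with CAFs, because the protocols name no other culture condition besides growth without them.

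The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 1.0, Cuffdiff 2.2.1 and the genome build hg19, without saying which step each served. The gene annotation, read filters and strand setting are not given in the sources used here. The authors deposited a single table of 26255 gene symbols with a signal value per library, which the file header calls a raw signal. These values behave as gene-level fragment counts divided by a size factor per library. In the 4 libraries, between 90.0% and 91.2% of the values above 0 were whole multiples, within 0.05 of a fragment, of a step that was the same for every gene of that library. That step, the value of 1 fragment, was 1.25 in the solid tumor, 1.39 in the acinar tumor, 0.795 in the single culture and 0.720 in the mix culture. The remaining values were fractional, for a cause that was not tested. Where genes overlap or are near-identical copies, the assignment of fragments between them is uncertain, and without a known strand setting so is one between a gene and its antisense partner. Because the values are not whole for every gene, no count model was fitted. The analysis plan had assumed FPKM. Its pseudocount and filters were set for values on about the CPM scale, so all 4 libraries were divided by the same constant, 8.94, which puts their mean total on that scale and keeps the authors' scaling between libraries. The resulting values are called scaled counts. They were not divided by gene length, so levels of different genes are not to be ranked against each other.

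With 1 library per group no difference has a replicate check, and no p-value is given. Acinar was compared with solid tumor and mix with single culture; the 2 comparisons share no library. Ratios were log2((value + 1)/(value + 1)) in scaled counts, over genes at 1 or more in at least one library of the pair, and genes at or past 2-fold on that scale were counted. This scale understates differences of low genes. The folds printed for single genes are plain ratios of the scaled counts. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals on the estimated fragments, given only for genes with whole fragments in both libraries. They cover counting error only, and fragments without molecular identifiers are not independent molecules. Counting noise was simulated with 100 draws of fragments with no difference within a pair. On simulated data with known answers, 97 genes were made to differ 2.83-fold and 103 genes 4-fold between the tumor libraries (13850 genes in the step). Of these, 95.9% and 100% passed the 2-fold limit. For the culture libraries 89 and 111 genes were made to differ (13405 genes in the step), and both shares were 100%. The shares hold for the genes made to differ and not for all genes analysed. They do not extend to low genes, whose differences this scale understates.

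Before the data were examined, 25 gene lists and 6 marker lists of other cell types were fixed, and all 830 of their entries matched a symbol in the table. The marker lists cover fibroblasts, endothelium, leukocytes, erythroid cells, muscle and fat, and skin keratinocytes. For a list with 5 or more measured members, the percentile of its median log2 ratio was taken among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above 97.5. Percentiles describe these libraries and are not a test across samples. Intervals of list medians are 95% bootstrap intervals over members (2000 draws).

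The rule for named genes was also fixed beforehand. Per comparison it takes the 12 highest and 12 lowest log2 ratios among genes at 5 scaled counts or more in at least one library and above 0 in both, leaving out small RNA, LOC and LINC symbols. It adds up to 4 members per list past 2-fold, key genes whatever their values (TGFBI, SMAD7, CDH1, CDH2, VIM, FN1, TGFB1 and NKX2-1), up to 5 genes listed at 0 in one library, up to 10 genes per direction that differed the same way in both comparisons and up to 5 per opposite pattern. Some genes that the rule names are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

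For each result 6 alternatives fixed in advance were computed: pseudocounts of 0.1 and 5, no filter, a filter of 5 scaled counts, libraries rescaled to the same total and pairs centred on their median gene. After the data were seen, 2 more were added: deposited values with no division by the common constant, and only genes with whole fragments in all 4 libraries. The reference genome at hand is GRCh38 and not hg19, so no coordinates are given; its transcripts served only for lengths. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.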

Results

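The 4 libraries describe A549 cells in 2 settings: solid-type against acinar-type tumor tissue from xenografts, and 3D colonies grown without CAFs (single culture) against colonies grown with them (mix culture). CAFs are the fibroblasts of a tumor's stroma, and an acinar tumor forms gland-like structures where a solid one grows as sheets. The estimated depth was about 7270000 fragments in the solid tumor, 6630000 in the acinar tumor, 10970000 in the single culture and 12180000 in the mix culture, so counting error was larger for the tumors. An upper limit of 3 fragments corresponded to 0.420, 0.465, 0.267 and 0.242 scaled counts in the same order, the scaled count being the deposited normalised count divided by a constant common to all libraries. Genes at 1 scaled count or more numbered 13638, 13467, 13256 and 13057. Across 14561 genes, log2 values correlated at r = 0.978 between the tumors and 0.987 between the cultures, against 0.856 to 0.867 between a tumor and a culture. Genes are not independent replicates, and each group is 1 library, so every difference below is between libraries and has no replicate check.

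The first comparison asks how tumor cells in acinar areas differ from those in solid areas, in a study whose title ties TGF-β signaling from CAFs to histology. In the acinar tumor, TGF-β target genes, inflammatory cytokine genes and cholesterol synthesis genes were higher, while hypoxia, glycolysis, ribosomal protein and gastrointestinal or liver lineage genes were lower. IL11, a cytokine gene induced by TGF-β, was 6.73-fold higher (14.1 against 2.10 scaled counts, 95% interval of the fold 3.87 to 12.5), and CA9, the hypoxia-induced carbonic anhydrase, was 7.10-fold lower (17.8 against 127 scaled counts, 5.84 to 8.69). Of 13979 genes, 277 were at least 2-fold higher and 357 at least 2-fold lower in the acinar tumor. The counts were 478 and 692 with a pseudocount of 0.1, and with one of 5 the balance turned, to 114 higher and 101 lower. Simulated counting noise alone gave at most 19 and 22 genes in 100 draws. Among these 277 and 357 genes, 48 of the higher and 56 of the lower did not have whole fragments in all 4 libraries.

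Of 31 measured TGF-β target genes, 27 had a ratio above 0, 8 were past 2-fold higher and 1 was past 2-fold lower. The list median was 0.47 (bootstrap interval 0.27 to 0.82), above all 10000 random lists. Besides IL11, TAGLN, which encodes the actin-binding protein transgelin, was 5.39-fold higher (47.4 against 8.81 scaled counts, 4.09 to 7.18). In the cultured A549 cells TAGLN was low, at 1.87 scaled counts in the single and 1.05 in the mix culture. CTGF, encoding a matrix-associated growth factor, was 3.68-fold higher (101 against 27.5 scaled counts, 3.13 to 4.34). TGFBI was 1.20-fold higher (1.14 to 1.26), and the SMAD7 interval included no difference (14.7 against 11.3 scaled counts, 0.957 to 1.77). The lipoprotein lipase inhibitor gene ANGPTL4 went the other way, at 50.1 against 161 scaled counts. TGF-β ligands, receptors and SMADs did not stand apart as a list (25 measured, median 0.07, percentile 77.5). Within it the receptor gene TGFBR1 was 2.24-fold higher (955 against 426 scaled counts, 2.15 to 2.34) and the integrin gene ITGAV 2.06-fold higher, whereas TGFB1 itself did not differ beyond counting error (33.6 and 32.0 scaled counts, fold 1.05, 0.869 to 1.27). Fibroblast markers moved in the same direction as the TGF-β targets (15 measured, median 0.30, percentile 99.7, 5 higher and 1 lower), a position lost with no filter on low values (percentile 97.2). The bootstrap interval of that median, -0.07 to 1.32, included 0. COL5A1 was 3.87-fold and LUM 2.83-fold higher and MFAP5 was at 563 against 225 scaled counts. The abundant fibroblast collagen COL1A1 was at 30.7 and 32.3 scaled counts and COL3A1 at 0.310 and 1.12 (both chosen after their values were seen).

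Mesenchymal genes of epithelial-mesenchymal transition (EMT) went both ways (20 measured, median -0.07, percentile 31.4, 3 higher and 1 lower). N-cadherin (CDH2) was 3.68-fold higher, at 86.5 against 23.5 scaled counts, and the gelatinase gene MMP2 4.74-fold higher (3.22 to 7.15). Fibronectin (FN1) was 2.87-fold lower, at 102 against 292 scaled counts (2.63 to 3.14). Vimentin (VIM) was at 1943 and 2135 scaled counts. E-cadherin (CDH1) did not differ beyond counting error (204 against 199 scaled counts, fold 1.03, 0.952 to 1.11). Epithelial junction and polarity genes had a median of 0.15 (-0.00 to 0.26) with no member past 2-fold among 33 and lay at percentile 97.7, a position lost under 3 alternatives, with the lowest percentile at 89.1.

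The basement membrane and integrin list had 5 of 25 measured genes past 2-fold higher and none lower (median 0.31, percentile 99.99). The collagen IV gene COL4A1 was 2.86-fold higher (17.2 against 6.01 scaled counts, 2.0 to 4.17). Proteases and the plasminogen system did not stand apart (22 measured, median 0.14, percentile 94.5), although the metalloprotease gene ADAM19 was 13.9-fold higher (15.5 against 1.12 scaled counts, 6.77 to 33.0).

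Inflammatory genes under NF-κB control were higher, with 10 of 30 measured past 2-fold higher and none lower (median 0.61, above all random lists). The monocyte chemokine gene CCL2 was 5.72-fold higher (15.2 against 2.66 scaled counts, 3.47 to 9.90), the neutrophil chemokine gene CXCL8 3.92-fold higher (195 against 49.8 scaled counts, 3.48 to 4.42) and IL32 3.25-fold higher (2.81 to 3.76). Cholesterol synthesis genes had the highest median of the 25 lists, 0.92 (0.62 to 1.02), with 23 of 24 above 0 and 8 past 2-fold higher. INSIG1, a sensor of sterol levels, was 2.67-fold higher (2.30 to 3.10), MSMO1 2.55-fold and HMGCS1 2.34-fold, the last 2 being enzymes of the pathway. Wnt and Notch genes stood apart on the higher side (24 measured, median 0.36, percentile 100) but had an interval that included 0 (-0.05 to 0.55), with 2 members past 2-fold higher and 3 lower. WNT7A was 4.93-fold higher (2.35 to 11.5) and the Wnt transcription factor gene TCF7 2.77-fold higher (2.11 to 3.67), while the receptor gene NOTCH3 was 7.02-fold lower (4.19 against 29.4 scaled counts, 4.69 to 10.9). S phase genes (30 measured, median 0.21, percentile 99.84), immediate early and dissociation genes (27, 0.21, 99.8) and EGFR ligands and ERK feedback genes (18, 0.20, 98.9) also stood apart, with no member past 2-fold higher. The intervals of the last 2 medians included 0 (-0.08 to 0.36 and -0.09 to 0.41). In the immediate early list the members past 2-fold were lower: FOS was 3.74-fold lower (3.18 to 4.41) and EGR1 2.82-fold lower (2.02 to 4.01).

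Gastrointestinal and liver lineage genes had the lowest median, -1.17 (-1.45 to -0.80), with 17 of 28 past 2-fold lower and 1 past 2-fold higher. The fibrinogen genes FGA, FGB and FGG, liver secretory genes that A549 cells express, were 3.66-fold, 3.86-fold and 3.82-fold lower, FGA being at 308 against 1128 scaled counts. All 25 measured hypoxia genes lay between -2.76 and 0.17 on the log2 scale, with 8 past 2-fold lower (median -0.73, below all random lists). After CA9, the adrenomedullin gene ADM was 3.67-fold lower (27.6 against 101 scaled counts, 3.11 to 4.35) and STC2 5.66-fold lower (2.97 to 11.9). Glycolysis genes had a median of -0.43, below all random lists, with 2 of 18 past 2-fold lower. These were the hexokinase gene HK2 (8.53 against 25.6 scaled counts, 3.00-fold) and the aldolase gene ALDOC (15.2 against 35.9 scaled counts, 2.37-fold). Unfolded protein and integrated stress response genes were lower as a list (28 measured, median -0.28, percentile 0.01, 2 past 2-fold lower), with DDIT4 at 349 against 708 scaled counts. All 33 measured ribosomal protein genes were below 0, none past 2-fold (median -0.40, -0.46 to -0.36, below all random lists).

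Outside the lists, genes with the largest ratios in the acinar tumor included the muscle protein gene IGFN1 (12.1-fold, 8.16 to 18.7), the keratin gene KRT6B (11.1-fold, 6.62 to 19.9), the intermediate filament gene NES (9.56-fold, 5.68 to 17.2) and WNT11 (7.92-fold, 3.57 to 20.7). The secretory granule gene CHGB was 13.4-fold lower (13.3 against 179 scaled counts, 10.8 to 16.9) and SNCG, encoding γ-synuclein, 9.53-fold lower (4.65 against 44.3 scaled counts, 6.54 to 14.4). The imprinted RNA H19 was at 1.55 against 78.0 scaled counts, but its fragments were not whole and the value is uncertain. PLVAP, an endothelial diaphragm gene, had 84 estimated fragments in the acinar tumor and was listed at 0 in the solid tumor. Of the 14 fixed endothelial markers, 1 was measured, and muscle and fat markers had 2 and erythroid markers 0 measured. Host cells of the xenografts are mouse cells, while the values stand under human symbols from a human genome build. Low values of these markers, and the leukocyte values that follow, therefore cannot show how much host tissue was present. Leukocyte markers were lower (7 measured, median -0.63, interval -1.02 to 0.08, percentile 0.65, but 3.13 with a pseudocount of 0.1), with CD14 at 2.64 against 9.65 scaled counts and LYZ at 23.9 against 49.4. Keratinocyte markers had 5 measured members and a median of 0.01, among them TP63, 3.15-fold higher at 38.3 against 12.2 scaled counts. Lung lineage (16 measured, median 0.00, percentile 52.7), G2/M (33, -0.01, 40.9), NRF2 target (33, 0.01, 39.1), interferon-stimulated (33, -0.05, 23.2), HLA and antigen presentation (17, -0.11, 7.99), p53 target (22, 0.05, 65.0), mitochondrial respiration (30, -0.07, 2.98) and reference housekeeping genes (24, 0.02, 47.1) did not stand apart. The lung lineage regulator NKX2-1 was at 0.155 scaled counts in the acinar tumor and listed at 0 in the other libraries.

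**Figure D1:**
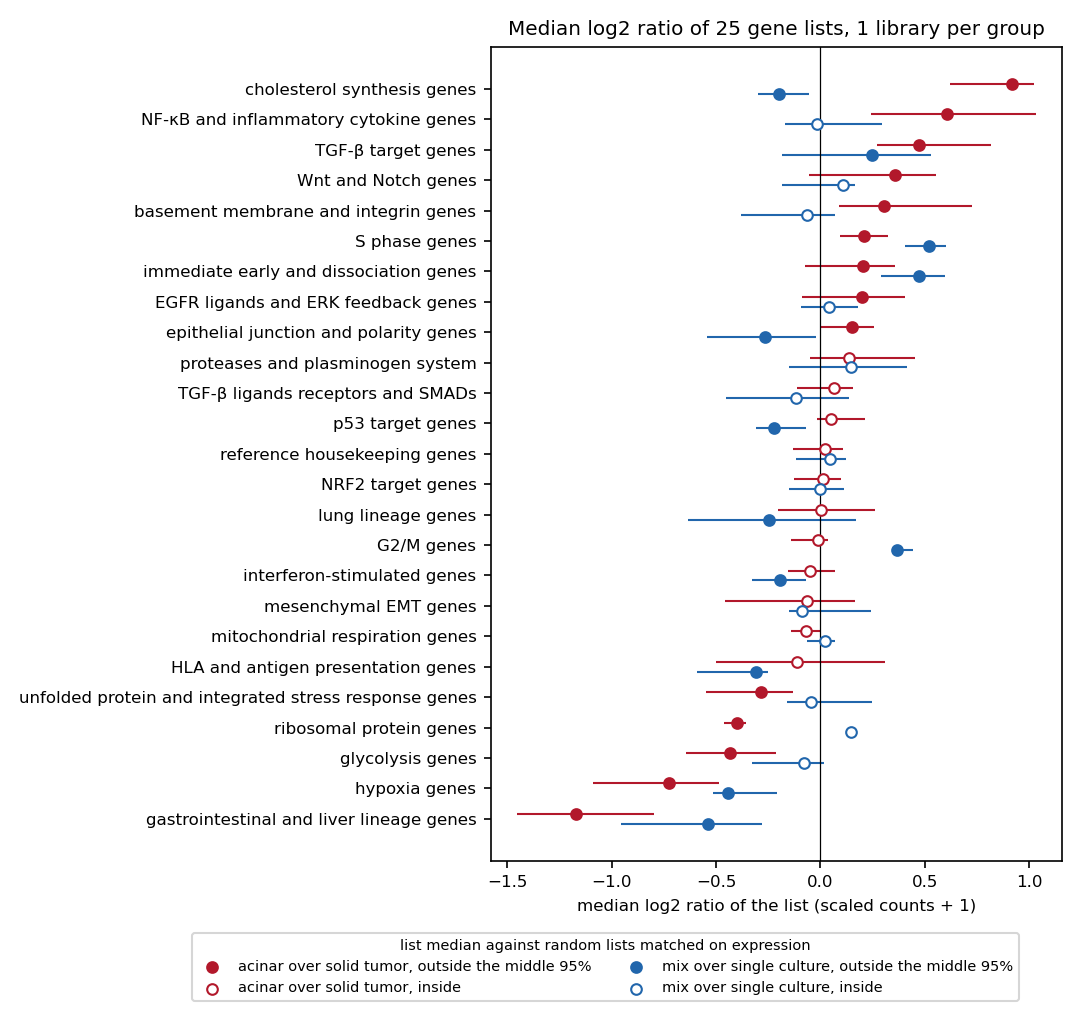
Median log2 ratio of each of the 25 gene lists in acinar over solid tumor (red) and mix over single culture (blue), with bootstrap 95% intervals over members; filled points lie outside the middle 95% of matched random lists. TGF-β targets lie above 0 in both (0.47 and 0.25), gastrointestinal and liver lineage genes below 0 in both (-1.17 and -0.54), and cholesterol synthesis genes on opposite sides (0.92 and -0.20).

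The second comparison asks what colony growth with CAFs does to the A549 cells. In the mix culture, TGF-β targets, cell cycle genes and immediate early genes were higher as lists, and gastrointestinal or liver lineage, hypoxia, epithelial junction, HLA and p53 target genes were lower. IL11 was 7.56-fold higher (72.5 against 9.60 scaled counts, 6.18 to 9.31) and CDH1 1.67-fold lower (120 against 200.5 scaled counts, 1.57 to 1.79). Of 13485 genes, 92 were at least 2-fold higher and 234 at least 2-fold lower, where counting noise alone gave at most 3 in either direction in 100 draws. The counts were 192 and 522 with a pseudocount of 0.1 and 33 and 73 with one of 5. Of the 92 and 234 genes, 25 of the higher and 36 of the lower did not have whole fragments in all 4 libraries.

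TGF-β targets were split, with 18 of 29 measured genes above 0, 5 past 2-fold higher and 2 past 2-fold lower. Their median of 0.25 lay above all random lists, but its bootstrap interval over members, -0.18 to 0.53, included 0. CYR61, a matrix-associated signaling protein gene, was 2.38-fold higher (38.3 against 16.1 scaled counts, 2.0 to 2.84) and CTGF 2.18-fold higher (26.5 against 12.2 scaled counts, 1.78 to 2.68). SMAD7, the inhibitory SMAD induced by the pathway, was 1.87-fold higher (8.29 against 4.44 scaled counts, 1.32 to 2.67) and TGFBI 1.36-fold higher (909 against 669 scaled counts, 1.32 to 1.40). ID3, which TGF-β represses in many epithelial cells, was 2.40-fold lower (36.5 against 87.6 scaled counts, 2.15 to 2.69). The other target past 2-fold lower was CDKN1A, at 125 against 254 scaled counts (chosen after its values were seen), a cell cycle inhibitor gene that TGF-β induces in many epithelial cells. TGFB1 did not differ beyond counting error (308 and 315 scaled counts, 1.02-fold lower, 0.974 to 1.07), and the ligand, receptor and SMAD list did not stand apart (26 measured, median -0.12, percentile 3.00), although it did on the lower side under 2 alternatives, a pseudocount of 5 and only genes with whole fragments (lowest percentile 1.29). Fibroblast markers had a median of -0.06 over 12 measured genes (percentile 18.0, 6 above 0 and 6 below, none past 2-fold). Among the fibroblast collagens, COL5A1 was at 285 against 176 scaled counts, COL1A1 at 29.5 against 19.3 and COL3A1 at 0.564 against 0.356 (chosen after their values were seen).

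Mesenchymal EMT genes again went both ways (23 measured, median -0.09, percentile 10.2) and stood apart on the lower side only with a filter of 5 scaled counts (percentile 1.95). The EMT transcription factor gene SNAI1 was 2.30-fold higher (9.42 against 4.09 scaled counts, 1.63 to 3.32), CDH2 1.19-fold higher (1.07 to 1.32) and VIM was at 1216 against 886 scaled counts, while FN1 was 2.99-fold lower (1136 against 3394 scaled counts, 2.93 to 3.05). Epithelial junction and polarity genes were lower as a list (28 measured, median -0.26, -0.55 to -0.02, percentile 0.03). Besides CDH1, the keratin gene KRT19 was 2.21-fold lower (15.1 against 33.4 scaled counts, 1.85 to 2.64), the only member past 2-fold. Basement membrane and integrin genes (28, -0.06, percentile 10.8) and proteases (19, 0.15, 95.4) did not stand apart. The protease list did so on the higher side under 3 alternatives, a pseudocount of 0.1, a filter of 5 scaled counts and undivided deposited values (highest percentile 99.6). Within it 13 members were above 0, the urokinase gene PLAU being at 108 against 50.7 scaled counts (fractional in the single culture), while MMP7 was 2.81-fold lower (2.03 to 3.94).

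All 30 S phase genes and all 33 G2/M genes had ratios above 0, none past 2-fold, with medians of 0.52 (0.41 to 0.60) and 0.37 (0.35 to 0.45), both above all random lists. Immediate early and dissociation genes had 23 of 27 above 0 and 4 past 2-fold higher (median 0.47, above all random lists). EGR1 was 3.09-fold higher (313 against 101 scaled counts, 2.90 to 3.31), NR4A1 3.15-fold, the phosphatase gene DUSP1 2.91-fold and FOS 2.0-fold higher (670 against 334 scaled counts).

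Among lists on the lower side, gastrointestinal and liver lineage genes had 20 of 21 below 0 and 6 past 2-fold lower (median -0.54, below all random lists), FGB being 7.73-fold lower (1.85 against 14.3 scaled counts, 4.97 to 12.5). Hypoxia genes had 21 of 25 below 0 and 1 past 2-fold lower (median -0.44, below all random lists), PPFIA4 at 14.7 against 34.8 scaled counts. HLA and antigen presentation genes (21 measured, median -0.31, percentile 0.06), cholesterol synthesis genes (24, -0.20, 0.01) and p53 targets (22, -0.22, below all random lists) were lower by less, with 0, 0 and 1 members past 2-fold. Interferon-stimulated genes (32, -0.19, percentile 0.83) included IFI6, 2.91-fold lower (2.33 to 3.65), and their position was lost with no filter on low values (percentile 2.83). Lung lineage genes (13, -0.25, interval -0.63 to 0.17, percentile 1.78) lost theirs under 2 alternatives, the highest percentile being 22.4. SOX2 in that list was 2.79-fold lower (5.23 against 14.6 scaled counts, 2.08 to 3.77). Glycolysis genes did not stand apart (18, -0.08, percentile 3.60), although HK2 was 5.26-fold lower (5.88 against 30.9 scaled counts, 4.08 to 6.87). Nor did NRF2 targets (32, -0.00, 18.4), NF-κB and cytokine genes (26, -0.02, 29.6), stress response genes (28, -0.05, 7.51), EGFR and ERK genes (18, 0.04, 57.1), Wnt and Notch genes (23, 0.11, 91.3), ribosomal protein genes (33, 0.15, 96.4, but 98.1 with no filter), mitochondrial respiration genes (30, 0.02, 29.5) and housekeeping genes (24, 0.05, 47.3). Leukocyte (6 measured, -0.01, 60.2) and keratinocyte markers (5, -0.33, 12.1) did not either, and 2 endothelial, 2 muscle and fat, and 0 erythroid markers were measured.

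The largest ratios in the mix culture included TERT, the catalytic subunit of telomerase, at 11.9 against 0.800 scaled counts (14.9-fold, 7.64 to 33.2), the Wnt-induced WISP1 (5.06-fold, 3.26 to 8.17), the neuropeptide precursor gene VGF (4.17-fold, 3.47 to 5.04) and IGF2 (4.06-fold, 3.07 to 5.44). The cell adhesion genes CEACAM1 and CEACAM6 were 9.74-fold and 5.79-fold lower, at 3.22 against 31.4 and 28.7 against 166 scaled counts. The secreted lipocalin gene LCN2 was 8.75-fold lower (4.89 to 17.0), RARRES1 6.0-fold (5.26 to 6.88) and the cobalamin carrier gene TCN1 5.51-fold lower (4.38 to 6.99). GPX2, an antioxidant enzyme gene, was 3.61-fold lower (61.1 against 221 scaled counts), and the secretory regulator XBP1 2.48-fold lower (146 against 363 scaled counts).

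**Figure D2:**
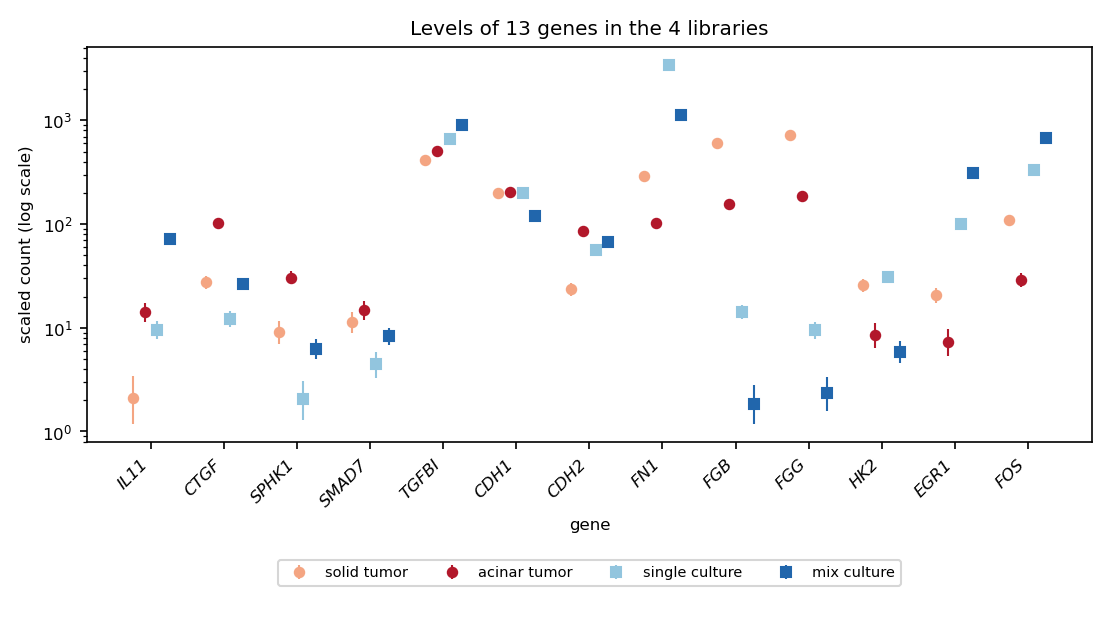
Scaled counts of 13 genes on a log axis in the solid tumor, acinar tumor, single culture and mix culture, with exact Poisson 95% intervals for counting error where fragments were whole; each point is 1 library. IL11 is higher in acinar than solid tumor (14.1 against 2.10) and in mix than single culture (72.5 against 9.60), FN1 lower in both, and EGR1 and FOS lower in the acinar tumor but higher in the mix culture.

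Setting the 2 comparisons side by side asks whether acinar tumor cells and cells grown with CAFs differ from their partners in the same genes. Over 12903 genes in both, the log2 ratios correlated weakly (Pearson r = 0.154, bootstrap 0.120 to 0.187, Spearman rho = 0.144), and 55.8% had the same sign. Past 2-fold, 7 genes were higher in both where independent lists would share 1.02, and 38 were lower in both against 3.66. These counts depended on the pseudocount, at 1 against 0.195 and 13 against 0.479 with one of 5, and 20 against 3.19 and 83 against 13.8 with one of 0.1. A filter of 5 scaled counts left 24 lower in both against 1.49. Opposite directions held 7 genes each, against 2.67 and 1.39 for independent lists. Several of them are symbols that join neighboring genes, such as SERF2-C15ORF63, CHKB-CPT1B, PHOSPHO2-KLHL23 and NME1-NME2, for which the assignment of fragments is uncertain. The genes higher in both were IL11, SPHK1, CTGF, IGFBP7, ANXA8, ANXA8L1 and PLSCR3. SPHK1, encoding sphingosine kinase, was 3.34-fold higher in the acinar tumor and 3.07-fold in the mix culture. ANXA8 (chosen after its values were seen) and ANXA8L1 are near-identical copies that can share fragments, and PLSCR3 and, in the tumors, IGFBP7 had fractional values. Genes lower in both included the transferrin gene TF (7.69-fold and 4.27-fold), the angiotensin receptor gene AGTR1 (5.56-fold and 3.94-fold), FGB, FGG, CREB3L1, ADCY5, FN1 and HK2. FOS, EGR1 and LRP4 (fractional in the cultures) were lower in the acinar tumor and higher in the mix culture, while PCDH1 and GPRC5B showed the opposite. In the gene lists that stood apart on the same side in both comparisons, shared directions were about as many as independent directions would give. Above 0 in both were 16 of 29 TGF-β targets, against 15.5. So were 21 of 30 S phase genes and 14 of 27 immediate early and dissociation genes, against 21 and 14.5. Below 0 in both were 18 of 25 hypoxia and 17 of 21 gastrointestinal and liver lineage genes, against 18.5 and 17.1. These counts had little room to come out otherwise, because most members lay on the same side in each comparison. Above 0 in acinar and in mix were 25 and 18 of the TGF-β targets, 3 and 4 of the hypoxia genes and 3 and 1 of the lineage genes. For S phase genes these were 21 and 30, and for immediate early and dissociation genes 17 and 23. The counts therefore do not tell whether the 2 comparisons share genes within these lists. Of the unfolded protein and integrated stress response genes, 14 of 28 were below 0 in both against 11.4, and of the NF-κB and cytokine genes 11 of 25 were above 0 in both against 8.80. These 2 lists stood apart in acinar over solid only and are named because their excess was the largest. Other lists lay nearer to independence or under it, such as interferon-stimulated genes, with 11 below 0 in both against 11.9.

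**Figure D3:**
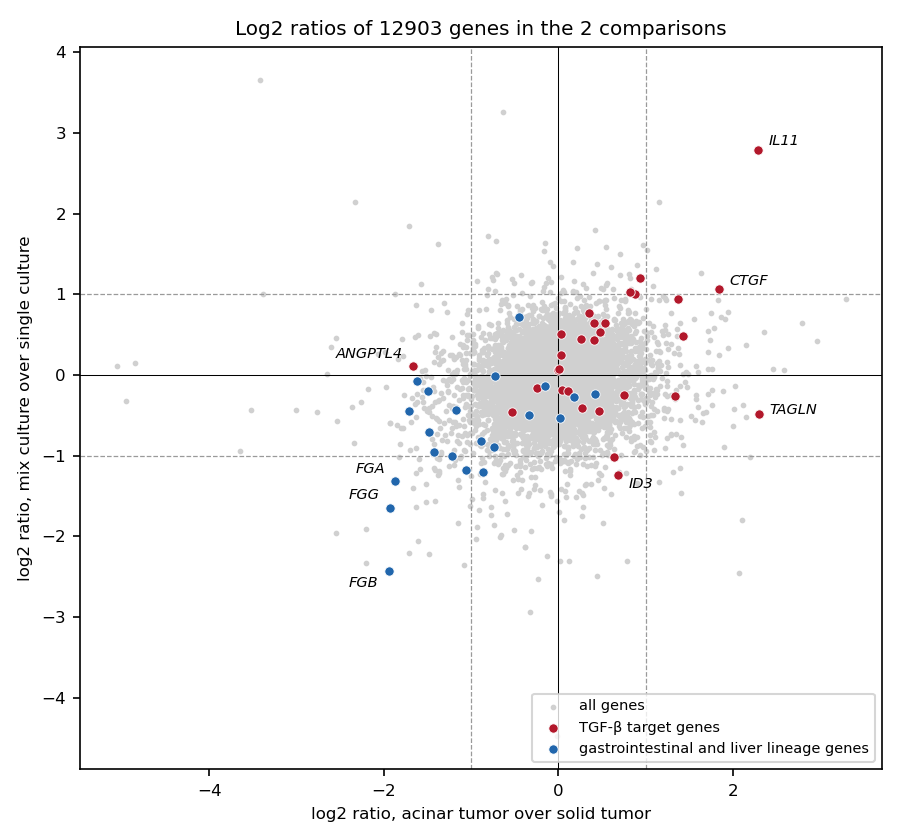
Log2 ratio of each of 12903 genes in acinar over solid tumor (x axis) and mix over single culture (y axis), with TGF-β targets in red, gastrointestinal and liver lineage genes in blue and dashed lines at 2-fold. IL11 and CTGF lie past 2-fold at the upper right, and FGA, FGB and FGG past 2-fold at the lower left.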

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

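The median of the TGF-β targets stayed above all random lists under all 8 alternatives in both comparisons (0.45 to 0.53 in acinar over solid, 0.23 to 0.44 in mix over single), and the correlation of the 2 comparisons stayed between 0.121 and 0.186. Of the lists that stood apart, 13 of 14 in acinar over solid and 10 of 12 in mix over single did so under every alternative. Of the lists that did not, 0 of 11 in acinar over solid and 4 of 13 in mix over single stood apart under at least 1 alternative. The counts of genes past 2-fold depended on how low values were treated, since a smaller pseudocount lets low genes pass and a larger one holds them back. For genes higher in acinar, lower in acinar, higher in mix, lower in mix, higher in both and lower in both, the counts of 277, 357, 92, 234, 7 and 38 became 478, 692, 192, 522, 20 and 83 with a pseudocount of 0.1, and 114, 101, 33, 73, 1 and 13 with a pseudocount of 5. Requiring 5 scaled counts gave 203 lower in acinar and 24 lower in both, since fewer genes entered. Leaving out the division by the common constant, an alternative added after the data were seen that makes both the pseudocount and the filter smaller against the values, gave 1321, 1970, 604, 1171, 87 and 287. Rescaling to equal totals, centring on the median gene and only genes with whole fragments kept every one of the 6 counts within 1.5 times. Removing the filter cannot change these counts, since with a pseudocount of 1 a gene below 1 in both libraries cannot pass 2-fold. No median of a list that stood apart changed sign, nor did a named gene's ratio under the pseudocounts and scalings, the filters leaving single ratios as they are. With a pseudocount of 5, 58 of 171 named gene ratios were counted as moved. That count holds ratios that moved by more than counting error and also any ratio without an interval that changed at all. Depth limits the tumor libraries most, and with 1 library per group neither a paired analysis nor leaving out a library was possible.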

Other observations

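The tests for fibroblast RNA, for fibroblasts carrying extra TERT and for dissociation stress were chosen after the results were seen; those for counting noise and transcript length were fixed before. The genes in the next paragraph were also chosen after their values were seen.

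Tumors and cultures differed far more than the groups within each. In both tumors 158 genes were at least 8-fold higher than in both cultures, and 62 were at least 8-fold lower, with 1 added to each value. The stratified-epithelium keratins KRT6A, KRT16 and KRT17 were far higher in the tumors than in the cultures, where they were near 0. KRT17 was at 729 scaled counts in the solid and 1771 in the acinar tumor, against 0.0889 in the single culture and listed at 0 in the mix culture. Not all such keratins were high in both tumors: in the solid tumor KRT6B was at 2.24 scaled counts and KRT14 was listed at 0. Between the tumors, KRT17 was higher in the acinar one by 2.43-fold (2.35 to 2.51), KRT16 by 2.36-fold (2.08 to 2.69) and KRT6A by 1.97-fold (1.83 to 2.12). CEACAM5, the carcinoembryonic antigen, was at 4670 and 4597 scaled counts in the tumors and at 1.51 and 0.242 in the cultures. In the other direction, LOXL2 was at 474 and 553 scaled counts in the single and mix cultures against 18.3 and 10.5 in the solid and acinar tumors, and TGFB1 at 315 and 308 against 32.0 and 33.6. Tumors were microdissected and cultures were sorted, so growth setting and preparation differ together here.

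As a list, TGF-β targets were higher in both the acinar tumor and the mix culture, beyond counting noise, under which the list median stayed below 0.0282 and 0.0264 in all but the highest draws, against 0.47 and 0.25 observed. Fibroblast RNA would bring collagen transcripts. The summed difference of COL1A1, COL1A2, COL3A1 and DCN was -0.00106 times that of the targets in the tumors and 0.0131 times in the cultures. With each value divided by transcript length, since levels of different genes are not comparable without it, these were -0.000561 and 0.00779. COL1A2, COL3A1 and DCN were each at 1.12 scaled counts or less in every library, so the test leans on COL1A1. It shows that COL1A1 did not rise with the targets in the tumors, at 30.7 against 32.3 scaled counts. In the mix culture COL1A1 was higher, at 29.5 against 19.3 in the single culture. Host fibroblasts of the xenografts are mouse cells, so values under human symbols cannot show how much of their RNA was present. A test that leans on 1 gene cannot exclude fibroblast RNA. Other fibroblast markers did go with the targets in the acinar tumor: LUM was at 55.4 against 19.6 scaled counts and MFAP5 at 563 against 225. FAP was at 2.17 against 0.420, while PDGFRB, THY1 and POSTN were listed at 0 in the acinar tumor (all chosen after their values were seen). A549 cells grown alone had LUM and MFAP5 listed at 0, and 12 of the 25 markers at 1 scaled count or more. The cultures are a poor guide to the tumor cells, since KRT17 too was at 0.0889 scaled counts in the single culture and 1771 in the acinar tumor. The source of these markers therefore stays open. Across genes, the Spearman rho of transcript length with the log2 ratio was 0.0350 in the tumors and -0.174 in the cultures. Removing this trend left medians of the TGF-β targets of 0.480 and 0.194, at percentiles 100 and 99.97. The epithelial junction, HLA, p53 and interferon lists were not checked in this way. Fibroblast RNA stays open, beside a response of the cancer cells to TGF-β and variation between single libraries, which were not tested. In the mix culture the interval of the median over members, -0.18 to 0.53, included 0.

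TERT was 14.9-fold higher in the mix culture. A possible explanation is carry-over from fibroblasts engineered to express it, although the cells were sorted for GFP and the sources used here do not say that the CAFs carried extra TERT. The summed increase of COL1A1, COL1A2, COL3A1 and DCN was 10.6 scaled counts against 11.1 for TERT, a ratio of 0.956 (0.576 after division by transcript length), of which COL1A1 gave 10.3 and the other 3 together 0.369. Both ratios lie between the level set for that source and the one set against it. They lean on COL1A1, which A549 cells grown without CAFs had at 19.3 scaled counts. In the mix culture COL1A2 was at 0.161 scaled counts, and DCN, MFAP5, FAP and POSTN were listed at 0. COL5A1 and THY1 were higher there than in the single culture, at 285 against 176 and 2.01 against 1.33 (markers chosen after their values were seen). The TERT level of such fibroblasts is not known, so carry-over and a difference in the A549 cells themselves cannot be told apart here.

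Immediate early genes were higher as a list in the mix culture. In the acinar tumor the list also stood apart on the higher side (median 0.21, interval -0.08 to 0.36), although FOS and EGR1 were lower. Dissociation and sorting stress could raise immediate early genes, and would be expected to raise heat shock genes too. Cells of both cultures were sorted, so such stress would have to differ between them, which the sources used here do not report. The median log2 ratio of 6 heat shock genes was 0.187 with 5 above 0, against 0.99 for 8 immediate early genes, all above 0. These 8 were picked from the fixed list, heat shock genes included, whose 27 measured members had a median of 0.47 with 4 below 0. The level set for a shared stress response was taken from the median of the 8, so it depends on that choice. The heat shock median lies under the level set for a shared stress response and above the one set against it. Unequal sorting stress and a response to CAFs therefore cannot be told apart here.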
